A study of Mus musculus with 23 samples.

How the data were processed

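The samples were sorted bone marrow cells of B6 mice, cultured with SCF (50 ng/ml), IL-3 (10), IL-6 (10), TPO (10) and FLT3L (20), transduced, and sorted for GFP 48 hours later, per the labels' protocols. Total RNA was extracted with TRIzol and libraries were made with the SMART-Seq v4 Ultra Low Input kit, per the labels' protocols. STAR, GATK and featureCounts were named in the submitters' processing notes, with mm10 as the genome. Raw counts of read pairs per gene were deposited: per the file headers, featureCounts 2.0.3 counted exons of a refGene annotation, grouped by gene, with primary alignments only, from BAM files with duplicates marked. No strand option was set, duplicates were not ignored, and overlaps were left at the default, per the file headers. The primary location of a read with several locations was thus counted, so close families (Ly6, Gimap, Serpina3, Oas, Ifit, histone and ribosomal protein genes) may share reads. The deposited table also gives each gene's exon length in bases, per the file headers.

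The planned design named all 23 samples, but the table holds 17 libraries. The 6 samples without a column were 2 of 3 HSC APOBEC-YTH, 2 of 3 MPP2 APOBEC-YTH, 1 of 2 MPP4 APOBEC-YTH and 1 of 3 MPP4 MIG samples, and they were not analysed. The table holds 25239 genes, 19153 of them with counts, and no mitochondrially encoded gene. Total counts were 37339303 to 50603800 per library. Between replicates the chi-square per degree of freedom was 9.43 to 50.6, where counting error alone would give 1.

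Counts were tested with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 15617. Library sizes were scaled with TMM factors, and 1 quasi-likelihood F test model with 8 group means and 9 residual degrees of freedom was fitted (prior degrees of freedom 5.72, common biological coefficient of variation 0.144). The comparisons were the construct effect (APOBEC-YTH against MIG) in each population, its average over 4 populations with equal weight, its difference between populations (an F test of 3 contrasts), and MPP1, MPP2 and MPP4 against HSC and MPP4 against MPP2 in MIG libraries. P values were adjusted by Benjamini and Hochberg within each comparison, and genes with adjusted p under 0.05 were called. CPM were computed from the counts with TMM factors. The 3 comparisons with HSC share the HSC MIG libraries, so their calls are not independent.

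Gene lists were written before the data were examined. Of 29 lists, 27 had at least 5 tested members. The mitochondrially encoded list had 0 of 13 members in the table, and the sex-linked list had 2 tested. Each list was tested with camera (correlation 0.01) in 9 comparisons, adjusted within a comparison's 27 lists, with an estimated correlation as an alternative, printed where it ends the call. The p at correlation 0.01 can be smaller by orders of magnitude than with an estimated correlation, also where the call stays. For the granulocyte and monocyte list the estimated correlation was 0.135 in the difference between the construct effects of HSC and MPP1. The size of a camera p at correlation 0.01 is thus no measure of the strength of evidence. Some genes belong to more than 1 list. Counts "adjusted over the list alone" apply the adjustment within the list's members. Where a list holds genes with 0 counts in a group, its median is also given with those genes at a bound of 3 counts over the group. Folds over 0 counts are given as "at least" with the same bound, and ratios over 1 to 3 counts with a 95% interval that covers counting error only.

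Genes were named by a rule fixed in advance. Apobec1, Ythdf2, Son and Myc were always reported in construct comparisons, and Slamf1, Cd48, Flt3, Cd34, Procr, Hlf and Mpl were always tested in population comparisons. Next came the 8 largest rises and falls among called genes with at least 10 CPM in the higher group and no overlap between libraries, without predicted genes. The average required 1 sign in all populations, and the difference between populations took the 8 smallest p. Last came up to 4 members per list with the smallest p. Some genes that met the rule are left out for length, in part because they lost their call under an alternative.

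The procedure was tested on simulated data with 100 genes changed by a log2 fold change of 1 and 100 by 2. It recovered 60% to 84% and 88% to 97% of them in the 4 construct comparisons, and 1.32% to 6.86% of calls were false over all comparisons. Every simulated library had the same spread per gene, and unchanged genes had 1 mean in all groups. The simulation thus assumes that the lone APOBEC-YTH libraries vary like the others, and its false share does not test that. Alternatives tried were RLE size factors, library size alone, no filter and a filter of 1 CPM in 3 libraries. Also tried were DESeq2 1.42.0 and limma voom with quality weights. An absolute log2 fold change of at least 1, fits of only the groups compared and a replicate block were tried too. Libraries were left out in turn, except the lone APOBEC-YTH libraries of HSC, MPP2 and MPP4. Population comparisons were repeated in APOBEC-YTH libraries and for the mean of both constructs. Lists were also tested with fry. Averaging without MPP2 was added after the data were seen.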

Results

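RNA was sequenced from 4 sorted populations of mouse bone marrow, hematopoietic stem cells (HSC) and the multipotent progenitors MPP1, MPP2 and MPP4, each transduced with 1 of 2 retroviruses that mark cells with GFP. The first, APOBEC-YTH, encodes a cytidine deaminase (APOBEC) joined to a YTH domain, the part of reader proteins that binds N6-methyladenosine (m6A) in RNA. In this assay, DART-seq, the deaminase edits C to U beside m6A. The second, MIG, is the empty vector. GFP-positive cells were sorted 48 hours after transduction. The deposited table gives counts per gene, so edits and m6A sites cannot be read from it, and the comparisons concern RNA levels only.

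Of 23 samples, 17 had a column of counts. HSC had 3 MIG libraries and 1 APOBEC-YTH library, MPP1 had 3 of each, MPP2 had 3 and 1, and MPP4 had 2 and 1. Total counts per library ran from 37339303 to 50603800. In a principal component analysis, PC1 carried 58.1% of the variance and set HSC and MPP1 libraries apart from MPP4 and MPP2 libraries, and PC2 carried 9.94%. Values after ± are standard errors for log2 fold changes and SDs between libraries for CPM (counts scaled to a common library size). The lone APOBEC-YTH libraries of HSC, MPP2 and MPP4 have no SD and were assumed to vary like the other groups. The labels do not say that replicates came from separate animals, so each p measures the spread between these samples, which may be technical. Positions are in the mm10 genome.

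The first question was how the populations differed under the empty vector. MPP1 libraries had lower stem cell, megakaryocyte and interferon response genes than HSC libraries and higher lymphoid and cell cycle genes. Flt3 (chromosome 5, 147330742 to 147400489), a receptor tyrosine kinase of early progenitors, had 96.1 ± 1.44 CPM in MPP1 and 20.5 ± 0.959 in HSC (n = 3 each), a log2 fold change of 2.23 ± 0.083. Procr (chromosome 2, 155751217 to 155755478), the protein C receptor that marks stem cells, had 36.8 ± 3.47 and 105 ± 6.62 CPM (-1.51 ± 0.086). Slamf1 (chromosome 1, 171767132 to 171801184), which encodes CD150, had 8.56 ± 0.306 and 27.2 ± 1.05 CPM (-1.67 ± 0.22). In all, 2970 of 15617 genes passed an adjusted p of 0.05, 1401 higher and 1569 lower, 585 of them by at least 2-fold.

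Stem cell genes were lower as a group, 0 higher and 24 lower of 34 (0 and 26 adjusted over the list alone), with a median log2 fold change of -0.92 and camera adjusted p = 2.37e-23. Beside Procr, Ly6a, which encodes Sca-1, changed by -2.11, Esam by -1.15, Hlf by -0.53 and the thrombopoietin receptor gene Mpl by -0.95. Interferon response genes showed the smallest p, 1 higher and 41 lower of 48 (1 and 43 adjusted over the list alone), with a median log2 fold change of -1.0003 and camera adjusted p = 8.84e-78. Irf7, a transcription factor of the interferon response, changed by -2.11, Ifi44 by -2.48, Oasl2 by -1.45, Isg15 by -2.28 and Oas2 by -2.45. The difference was small between APOBEC-YTH libraries. Against the lone HSC APOBEC-YTH library, the list's median log2 difference was -0.140 to -0.189 in MPP1 APOBEC-YTH libraries. It was 0.739 to 0.817 in HSC MIG libraries, which also serve as controls of the construct comparison in HSC. Inflammatory genes were also lower, 1 higher and 13 lower of 24 (2 and 13 adjusted over the list alone), with a median log2 fold change of -0.88 and camera adjusted p = 1.25e-09, including the NF-kB subunits Relb (-2.14) and Nfkb2 (-1.35). Megakaryocyte genes counted 2 higher and 14 lower of 25 (2 and 15 adjusted over the list alone), with a median log2 fold change of -0.77 (or -0.53 with genes at 0 counts set at their bound) and camera adjusted p = 1.25e-09, among them Selp (-1.53) and the platelet chemokine Pf4 (-1.43), while Thbs1 rose by 1.76.

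Lymphoid genes were higher, 11 higher and 3 lower of 29 (11 and 4 adjusted over the list alone), with a median log2 fold change of 0.39 (or 0.31 with genes at 0 counts set at their bound) and camera adjusted p = 3.07e-08. Dntt (chromosome 19, 41029275 to 41059525), which encodes terminal deoxynucleotidyl transferase, rose by 4.11 ± 0.19, Satb1 by 2.23 and Sell, which encodes L-selectin, by 1.197. Granulocyte and monocyte genes moved both ways, 20 higher and 13 lower of 42 (20 and 15 adjusted over the list alone), with a median log2 fold change of 0.14 and camera adjusted p = 1.48e-09. Mpo (chromosome 11, 87793784 to 87804412), the gene of myeloperoxidase, had 776 ± 29.9 CPM in MPP1 and 179.8 ± 18.2 in HSC (2.11 ± 0.067), and Irf8 (1.95), Ctsg (1.74) and Ccr2 (2.24) were also higher. S phase genes counted 22 higher and 0 lower of 43 (29 and 0 adjusted over the list alone), with a median log2 fold change of 0.28 and camera adjusted p = 9.61e-12. G2 and M phase genes counted 31 higher and 1 lower of 51 (35 and 1 adjusted over the list alone), with a median log2 fold change of 0.28 and camera adjusted p = 4.50e-15, including Top2a (0.52). MYC target and ribosome biogenesis genes counted 23 higher and 0 lower of 42 (27 and 0 adjusted over the list alone), with a median log2 fold change of 0.22 and camera adjusted p = 3.86e-10, and Myc itself rose by 0.69. Without MPP1 MIG replicate 1 the count of calls was 1948 and without replicate 3 it was 1905, and in APOBEC-YTH libraries it was 608. Eid2, Snx20 and Crls1 were among the 8 largest falls (-4.03, -2.46 and -2.44), but their adjusted p was 0.0623, 0.255 and 0.283 without HSC MIG replicate 3.

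Libraries labelled MPP2 differed from HSC libraries by granulocyte, mast cell and eosinophil genes at high levels and by low stem cell genes. Mpo had 11406 ± 259 CPM in MPP2 against 179.8 ± 18.2 in HSC (n = 3 each, 5.99 ± 0.080). Slamf1 had 2.32 ± 0.860 against 27.2 ± 1.05 CPM (-3.55 ± 0.25) and Procr had 5.70 ± 0.176 against 105 ± 6.62 (-4.20 ± 0.099). With Slamf1 so low and Mpo so high, it is in doubt whether the cells sequenced were still MPP2, so MPP2 stands for the label throughout. In all, 8770 of 15617 genes passed an adjusted p of 0.05, 4123 higher and 4647 lower, 3817 of them by at least 2-fold.

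Granulocyte and monocyte genes were higher without exception, 42 higher and 0 lower of 42 (42 and 0 adjusted over the list alone), with a median log2 fold change of 5.51 and camera adjusted p = 6.47e-140. Ctsg changed by 5.48, the collagenase gene Mmp8 by 6.83 and Anxa3 by 4.58. Mast cell, basophil and eosinophil genes were higher too, 28 higher and 0 lower of 31 (28 and 0 adjusted over the list alone), with a median log2 fold change of 4.88 (or 4.02 with genes at 0 counts set at their bound) and camera adjusted p = 3.44e-23, including Cpa3, a mast cell carboxypeptidase, at 5.22. Several highly expressed genes had no count in the HSC MIG libraries. Against a floor of 3 counts over the group, the basophil protease gene Prss34 was at least 8764-fold higher, the eosinophil peroxidase gene Epx at least 3490-fold, Cdh1, which encodes E-cadherin, at least 3192-fold, Mmp12 at least 1589-fold, Car4 at least 1268-fold and Tph1 at least 661-fold. Prg2, with 1 count in HSC MIG, had a ratio of 20830 with a 95% interval of 3738 to 822771. Dendritic cell genes counted 20 higher and 2 lower of 26 (20 and 2 adjusted over the list alone), with a median log2 fold change of 3.10 and camera adjusted p = 1.08e-15, and macrophage genes 9 higher and 2 lower of 12 (9 and 2 adjusted over the list alone), with a median log2 fold change of 3.25 and camera adjusted p = 0.000250. Interferon response genes were higher here, 45 higher and 1 lower of 48 (45 and 1 adjusted over the list alone), with a median log2 fold change of 1.43 and camera adjusted p = 4.68e-27, including Irf7 (3.59) and Usp18 (3.09).

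Stem cell genes were lower, 6 higher and 26 lower of 34 (6 and 26 adjusted over the list alone), with a median log2 fold change of -2.32 and camera adjusted p = 1.96e-17. Hlf changed by -2.84, Mpl by -3.65, Mycn by -2.75, Esam by -3.73, Fgd5 by -5.33 and the imprinted gene Ndn by -5.24. Among the largest falls outside the list were Mpdz (-6.10), Fhl1 (-5.87) and Tmem47 (-5.48). Flt3 was higher (1.35) and Cd34 lower (-0.34). Glycolysis genes counted 19 higher and 2 lower of 22 (20 and 2 adjusted over the list alone), with a median log2 fold change of 0.72 and camera adjusted p = 6.71e-11. MYC target and ribosome biogenesis genes counted 2 higher and 31 lower of 42 (2 and 31 adjusted over the list alone), with a median log2 fold change of -0.42 and camera adjusted p = 0.000204, and cholesterol synthesis genes 2 higher and 15 lower of 22 (2 and 15 adjusted over the list alone), with a median log2 fold change of -0.58 and camera adjusted p = 3.80e-05. Calls were 47.0% higher with TMM factors and 26.0% higher with library size alone, which moved the median of all genes to -0.39, and Cd48 (0.33 ± 0.090) was then no longer called (adjusted p = 0.894).

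MPP4 libraries (n = 2) had high Flt3, lymphoid, dendritic cell and granulocyte genes against HSC libraries (n = 3) and low stem cell and megakaryocyte genes. Flt3 had 131 ± 5.07 against 20.5 ± 0.959 CPM (2.67 ± 0.089), Dntt 35.1 ± 0.844 against 1.47 ± 0.310 (4.57 ± 0.20) and Slamf1 0.174 ± 0.161 against 27.2 ± 1.05 (-7.37 ± 0.40). In all, 5868 of 15617 genes passed an adjusted p of 0.05, 2839 higher and 3029 lower, 2431 of them by at least 2-fold.

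Lymphoid genes counted 19 higher and 2 lower of 29 (20 and 2 adjusted over the list alone), with a median log2 fold change of 2.14 and camera adjusted p = 5.91e-13. Sell changed by 3.28, Cd52 by 3.47, the chemokine receptor gene Ccr7 by 6.96 and Jchain, the immunoglobulin J chain, by 6.33. Ly6d, an early marker of the B lineage with 3 counts in HSC MIG, had a ratio of 643 with a 95% interval of 219 to 3120. Dendritic cell genes counted 19 higher and 2 lower of 26 (19 and 2 adjusted over the list alone), with a median log2 fold change of 2.60 and camera adjusted p = 2.43e-28, including Irf8 (4.17), the MHC class II gene H2-Aa (4.24) and its chaperone Cd74 (3.68). Granulocyte and monocyte genes counted 38 higher and 1 lower of 42 (39 and 1 adjusted over the list alone), with a median log2 fold change of 2.72 and camera adjusted p = 7.15e-109, and Mpo had 5898 ± 261 CPM (5.04). Interferon response genes counted 45 higher and 0 lower of 48 (45 and 0 adjusted over the list alone), with a median log2 fold change of 0.92 and camera adjusted p = 2.99e-30, including Stat1 (1.90). Genes of the integrated stress and unfolded protein responses counted 31 higher and 1 lower of 36 (32 and 2 adjusted over the list alone), with a median log2 fold change of 0.81 and camera adjusted p = 6.19e-28, including the chaperone gene Hspa5 (1.01).

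Stem cell genes counted 3 higher and 28 lower of 34 (3 and 29 adjusted over the list alone), with a median log2 fold change of -2.21 and camera adjusted p = 1.26e-28. Procr changed by -4.42, Hlf by -2.90 and Mycn by -1.78. Megakaryocyte genes counted 1 higher and 18 lower of 25 (1 and 18 adjusted over the list alone), with a median log2 fold change of -1.90 and camera adjusted p = 4.47e-19, including Cavin2 (-6.98), Mpl (-5.45) and Selp (-4.40). Mpdz had no count in MPP4 MIG and was at least 333-fold lower, and the cilium genes Evc and Evc2 changed by -8.40 and -6.42. Erythroid genes counted 1 higher and 13 lower of 34 (1 and 13 adjusted over the list alone), with a median log2 fold change of -0.41 (or -0.36 with genes at 0 counts set at their bound) and camera adjusted p = 2.03e-05, including Car2 (-2.22) and Apoe (-5.08). In APOBEC-YTH libraries 3903 genes were called, and with library size alone 32.5% of calls were higher, against 48.4% with TMM factors.

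The libraries labelled MPP4 and MPP2 were also compared directly. MPP4 (n = 2) had lower granulocyte, mast cell, macrophage and megakaryocyte genes than MPP2 (n = 3) and higher Dntt, Flt3 and ribosome biogenesis genes. Chil3, a chitinase-like protein of neutrophils and macrophages, had 13.98 ± 1.38 against 1669.9 ± 189 CPM (-6.90 ± 0.30), and Dntt had 35.1 ± 0.844 against 4.05 ± 0.356 (3.11 ± 0.19). In all, 5397 of 15617 genes passed an adjusted p of 0.05, 2557 higher and 2840 lower, 1556 of them by at least 2-fold.

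Of the falls, granulocyte and monocyte genes counted 1 higher and 39 lower of 42 (1 and 39 adjusted over the list alone), with a median log2 fold change of -1.63 and camera adjusted p = 3.75e-77, including Ngp (-5.71), S100a8 (-4.98) and Lyz2 (-3.60). Mast cell, basophil and eosinophil genes counted 0 higher and 27 lower of 31 (0 and 28 adjusted over the list alone), with a median log2 fold change of -2.52 and camera adjusted p = 9.61e-27, including Epx (-5.95) and Gzmb, which encodes granzyme B (-2.32). Macrophage genes counted 2 higher and 10 lower of 12 (2 and 10 adjusted over the list alone), with a median log2 fold change of -2.59 and camera adjusted p = 2.34e-06, and outside the list Arg1, which encodes arginase 1 (-10.01), and Mafb (-7.73) were among the largest falls. Megakaryocyte genes counted 0 higher and 19 lower of 25 (0 and 20 adjusted over the list alone), with a median log2 fold change of -1.43 and camera adjusted p = 6.51e-13, and Slamf1 changed by -3.83. Lymphoid genes counted 12 higher and 5 lower of 29 (13 and 6 adjusted over the list alone), with a median log2 fold change of 0.32 and camera adjusted p = 0.0456 (0.0743 with an estimated correlation), including Cd27 (1.58) and Flt3 (1.32), while Ets1 was lower (-3.52). Cx3cr1 (2.39), Epb41l3 (2.40), Zfp521 (2.03) and Id3 (1.93) were among the largest rises. MYC target and ribosome biogenesis genes counted 40 higher and 0 lower of 42 (41 and 0 adjusted over the list alone), with a median log2 fold change of 0.52 and camera adjusted p = 2.42e-19, including Ncl (0.69), and S phase genes 31 higher and 0 lower of 43 (32 and 1 adjusted over the list alone), with a median log2 fold change of 0.46 and camera adjusted p = 6.69e-11. Procr (-0.21 ± 0.11, adjusted p = 0.154) and Hlf (-0.056 ± 0.12, 0.769) did not pass. With library size alone 68.3% of calls were higher, against 47.4% with TMM factors, and the median of all genes moved to 0.16.

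**Figure D1:**
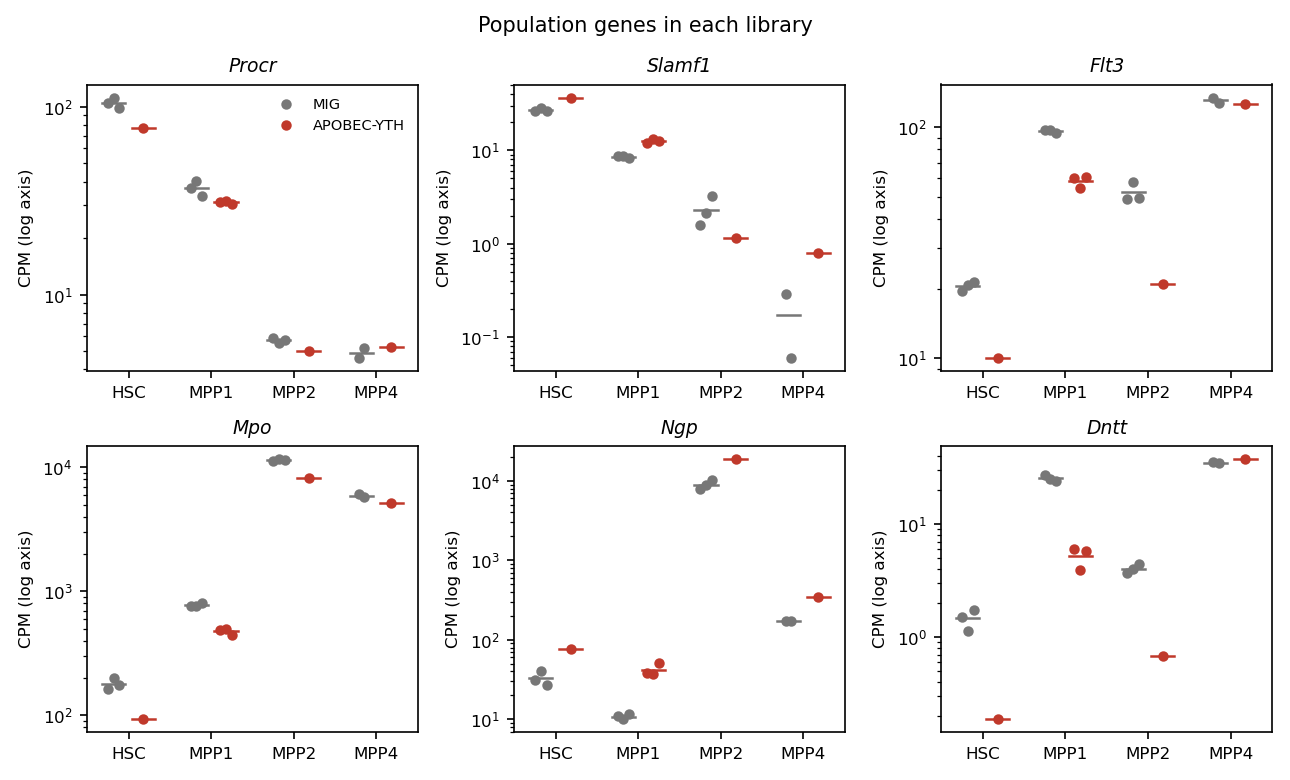
CPM of Procr, Slamf1, Flt3, Mpo, Ngp and Dntt in each library on a log axis, by population, with MIG libraries in grey, APOBEC-YTH libraries in red and a bar at each group's mean. Procr and Slamf1 are highest in HSC, Mpo and Ngp are highest in MPP2, and Dntt is highest in MPP4.

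The second question was what happened to RNA levels when the editing fusion took the place of the empty vector. In HSC, the APOBEC-YTH library (n = 1) had lower interferon response genes than the MIG libraries (n = 3) and higher megakaryocyte, mitotic and immediate early genes. Irf7 (chromosome 7, 141263183 to 141266424) had 20.4 CPM against 73.0 ± 8.28 (-1.84 ± 0.15, adjusted p = 2.64e-05). Ifi44 (chromosome 3, 151730923 to 151749910) had 13.5 against 52.5 ± 3.12 (-1.96 ± 0.14, adjusted p = 7.54e-06). Cavin2, a caveolar coat gene of platelets, had 72.4 against 28.8 ± 1.82 (1.33 ± 0.19). In all, 380 of 15617 genes passed an adjusted p of 0.05, 172 higher and 208 lower, 95 of them by at least 2-fold.

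Interferon response genes counted 0 higher and 33 lower of 48 (0 and 36 adjusted over the list alone), with a median log2 fold change of -0.76 and camera adjusted p = 1.73e-66. Isg15 changed by -1.95, Oasl1 by -1.91, Ifit1 by -1.64 and, outside the list, Phf11d by -1.85. Oas2 changed by -2.13, with adjusted p = 0.0703 without HSC MIG replicate 1 and 0.0664 without replicate 2. Dendritic cell genes counted 0 higher and 3 lower of 26 (0 and 6 adjusted over the list alone), with a median log2 fold change of -0.25 (or -0.17 with genes at 0 counts set at their bound) and camera adjusted p = 0.00121, including Bst2 (-1.09), which is also an interferon gene. Mast cell, basophil and eosinophil genes counted 2 higher and 4 lower of 31 (2 and 8 adjusted over the list alone), with a median log2 fold change of -0.74 (or -0.22 with genes at 0 counts set at their bound) and camera adjusted p = 0.000156, including Cpa3 (-2.59 ± 0.23). Flt3 changed by -1.03, Mpo by -0.96, Plac8 by -1.70 and Dntt by -2.95. The granulocyte and monocyte list as a whole counted 5 higher and 10 lower of 42 (9 and 14 adjusted over the list alone), with a median log2 fold change of -0.038 and camera adjusted p = 0.00535 (0.294 with an estimated correlation).

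Megakaryocyte genes were higher, 6 higher and 0 lower of 25 (10 and 0 adjusted over the list alone), with a median log2 fold change of 0.44 and camera adjusted p = 2.74e-12, including Itga2b, which encodes CD41 (0.64), Selp (0.79) and Treml1 (1.32). G2 and M phase genes counted 14 higher and 0 lower of 51 (30 and 0 adjusted over the list alone), with a median log2 fold change of 0.29 and camera adjusted p = 5.33e-18, including the spindle gene Tpx2 (0.57) and Ttk (0.60). Immediate early genes counted 5 higher and 0 lower of 26 (9 and 1 adjusted over the list alone), with a median log2 fold change of 0.069 (or 0.099 with genes at 0 counts set at their bound) and camera adjusted p = 9.51e-06, including Junb (0.99), Egr1 (1.03), Nfkbia (1.04) and Nfkbiz (1.55). The largest rises held Chil3 (2.50 ± 0.32), the gelatinase gene Mmp9 (1.81), the NADPH oxidase gene Cybb (1.69) and Cd177 (1.64), all known from neutrophils, with Nt5e (1.62) and Camkk1 (1.60). Stress response genes counted 8 higher and 0 lower of 36 (13 and 3 adjusted over the list alone), with a median log2 fold change of 0.15 and camera adjusted p = 1.79e-06 (0.0547 with an estimated correlation), including Asns (0.66), and glycolysis genes 5 higher and 0 lower of 22 (8 and 1 adjusted over the list alone), with a median log2 fold change of 0.13 and camera adjusted p = 8.92e-06 (0.111 with an estimated correlation), including Slc2a3 (0.78).

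No ribosomal protein gene was called in HSC over all genes tested, and 69 of 75 were lower adjusted over the list alone, with a median log2 fold change of -0.56 and camera adjusted p = 2.51e-29 (0.180 with an estimated correlation). Respiratory chain genes had a median log2 fold change of -0.35 and camera adjusted p = 1.73e-06 (0.376 with an estimated correlation). Replication-dependent histone genes had a median log2 fold change of -0.50 and camera adjusted p = 0.000865 (0.294 with an estimated correlation). These lists hold short genes, and the comparison as a whole had a median of -0.20 for the third of genes with the shortest exons and 0.080 for the longest. Apobec1 (-0.35 ± 0.13, adjusted p = 0.198), Ythdf2 (0.15 ± 0.094, 0.462), Son (0.014 ± 0.094, 0.976) and Myc (-0.0095 ± 0.078, 0.983) did not pass. The labels do not give the fusion's sequence, so counts at Apobec1 and Ythdf2 do not measure it. Without HSC MIG replicate 1 the count of calls was 244 and without replicate 2 it was 211. A fit of only these 4 libraries called 27, DESeq2 called 1020 and limma voom 706.

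MPP1, with 3 libraries of each construct, had the only replicated construct comparison. APOBEC-YTH libraries had lower cholesterol synthesis genes, higher stem cell, megakaryocyte and inflammatory genes, and higher neutrophil granule genes at low levels. Hmgcs1 (chromosome 13, 119690351 to 119708260), an enzyme gene of the mevalonate pathway, had 355 ± 15.4 CPM against 564 ± 18.1 (n = 3 each, -0.67 ± 0.056, adjusted p = 5.03e-06). Ngp (chromosome 9, 110419808 to 110423012), a neutrophil granule protein, had 42.2 ± 7.67 against 10.8 ± 0.814 (1.97 ± 0.15, adjusted p = 3.05e-06). Dntt had 5.25 ± 1.17 against 25.5 ± 1.45 (-2.28 ± 0.17, adjusted p = 2.71e-06). In all, 949 of 15617 genes passed an adjusted p of 0.05, 491 higher and 458 lower, 128 of them by at least 2-fold.

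Cholesterol synthesis genes counted 0 higher and 18 lower of 22 (0 and 20 adjusted over the list alone), with a median log2 fold change of -0.42 and camera adjusted p = 2.09e-29. Sqle changed by -0.42, Lss by -0.49 and Dhcr24 by -0.76. Stem cell genes counted 11 higher and 0 lower of 34 (15 and 1 adjusted over the list alone), with a median log2 fold change of 0.31 and camera adjusted p = 8.70e-13, including Gata2 (0.67), Tgm2 (0.87), Mycn (0.53) and Trpc6 (0.85). Megakaryocyte genes counted 9 higher and 1 lower of 25 (11 and 1 adjusted over the list alone), with a median log2 fold change of 0.34 (or 0.30 with genes at 0 counts set at their bound) and camera adjusted p = 3.11e-11, including Pf4 (0.94), Ppbp (1.19) and Selp (0.85). Inflammatory genes counted 8 higher and 0 lower of 24 (10 and 1 adjusted over the list alone), with a median log2 fold change of 0.31 and camera adjusted p = 2.36e-09, including Relb (1.17), Nfkbia (0.84) and Ccl5 (1.47). Immediate early genes counted 6 higher and 0 lower of 26 (8 and 1 adjusted over the list alone), with a median log2 fold change of 0.17 and camera adjusted p = 2.63e-05, including Egr1 (1.15) and Klf2 (1.39). p53 target genes counted 6 higher and 1 lower of 33 (7 and 2 adjusted over the list alone), with a median log2 fold change of 0.13 and camera adjusted p = 0.00238, including Plk2 (0.70) and Fas (0.74).

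Lymphoid genes counted 2 higher and 4 lower of 29 (2 and 4 adjusted over the list alone), with a median log2 fold change of -0.089 and camera adjusted p = 0.00662, including Flt3 (-0.72), Sell (-0.55) and Cd27 (-0.48). S phase genes counted 0 higher and 11 lower of 43 (0 and 20 adjusted over the list alone), with a median log2 fold change of -0.17 and camera adjusted p = 7.75e-10, including Fen1 (-0.35) and Mcm4 (-0.31). MYC target and ribosome biogenesis genes counted 0 higher and 4 lower of 42 (0 and 11 adjusted over the list alone), with a median log2 fold change of -0.12 and camera adjusted p = 1.77e-06. Both directions were seen for granulocyte and monocyte genes, 8 higher and 9 lower of 42 (12 and 12 adjusted over the list alone), with a median log2 fold change of 0.050 and camera adjusted p = 0.00563 (0.342 with an estimated correlation). In that list Mmp8 (2.27), Lcn2 (1.75), S100a8 (1.84) and S100a9 (1.85), which belong to neutrophil granules and cytosol, were higher, and the chemokine gene Ccl9 was lower (-0.91). Among the largest rises were Hic1 (3.59), Ahrr, a repressor of the aryl hydrocarbon receptor (2.99), and Dlk1 (1.89). Falls included Ly9 (-1.57), Lgals1, which encodes galectin 1 (-1.26), Emp1 (-1.12) and Aatk (-1.12). Cd74 (1.44) and H2-Aa (1.17) of the MHC class II pathway were higher.

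Interferon response genes counted 8 higher and 7 lower of 48 (8 and 10 adjusted over the list alone) in MPP1, with a median log2 fold change of 0.023 and camera adjusted p = 0.836. The effect on this list differed between HSC and MPP1 by a median of -0.77 (camera adjusted p = 1.61e-06 with an estimated correlation). Apobec1 (0.11 ± 0.093, adjusted p = 0.573), Ythdf2 (0.049 ± 0.067, 0.770), Son (-0.22 ± 0.067, 0.0668) and Myc (-0.15 ± 0.055, 0.137) did not pass, though Son did with DESeq2 (adjusted p = 0.0135) and without APOBEC-YTH replicate 1 (0.0291), and Myc did without APOBEC-YTH replicate 2 (0.0229). The count of calls was 525 and 505 without MIG replicate 1 or 3 and 616 and 581 without APOBEC-YTH replicate 2 or 3. DESeq2 called 1535 genes and limma voom 1628.

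In MPP2, the APOBEC-YTH library (n = 1) had higher granulocyte and mitotic genes than the MIG libraries (n = 3) and lower mast cell, erythroid, megakaryocyte and stem cell genes. Gzmb had 58.7 CPM against 250.1 ± 22.6 (-2.09 ± 0.11, adjusted p = 7.56e-08). Lcn2 (chromosome 2, 32384637 to 32387739), a neutrophil granule lipocalin, had 3445 against 1592 ± 269 (1.11 ± 0.15, adjusted p = 0.000183). Cpa3 (chromosome 3, 20215616 to 20242181) had 56.97 against 193 ± 12.9 (-1.76 ± 0.16, adjusted p = 7.83e-06). In all, 2559 of 15617 genes passed an adjusted p of 0.05, 1305 higher and 1254 lower, 656 of them by at least 2-fold.

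The rises in MPP2 held granulocyte and monocyte genes, 23 higher and 4 lower of 42 (25 and 7 adjusted over the list alone), with a median log2 fold change of 0.56 and camera adjusted p = 1.73e-10, including Mmp8 (1.37), Cebpd (1.46) and Lyz2 (0.99). G2 and M phase genes counted 29 higher and 0 lower of 51 (40 and 0 adjusted over the list alone), with a median log2 fold change of 0.42 and camera adjusted p = 2.67e-15, including Mki67 (0.90) and Tpx2 (0.66). Fn1, which encodes fibronectin (2.89), Asprv1 (2.77), Ly6i (2.29), Bcl6 (2.10), Il1f9 (2.07) and Nrp2 (2.04) were among the largest rises.

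Mast cell, basophil and eosinophil genes counted 1 higher and 15 lower of 31 (1 and 16 adjusted over the list alone) in MPP2, with a median log2 fold change of -0.81 and camera adjusted p = 4.37e-12, including Slc18a2 (-1.42) and Cyp11a1 (-1.06). Outside the list, Tph1, the first enzyme of serotonin synthesis (-2.92), was among the largest falls. So was Ccl24 (-3.63), which encodes a chemokine that acts on eosinophils and is not counted here as a gene of these cells. Erythroid genes counted 2 higher and 16 lower of 34 (2 and 17 adjusted over the list alone), with a median log2 fold change of -1.04 (or -0.99 with genes at 0 counts set at their bound) and camera adjusted p = 2.92e-07, including the transcription factors Gata1 (-1.41) and Gfi1b (-1.04). Megakaryocyte genes counted 2 higher and 10 lower of 25 (2 and 14 adjusted over the list alone), with a median log2 fold change of -0.73 (or -0.69 with genes at 0 counts set at their bound) and camera adjusted p = 5.52e-08, including Itga2b (-1.11) and Gp5 (-1.53). Stem cell genes counted 0 higher and 10 lower of 34 (0 and 10 adjusted over the list alone), with a median log2 fold change of -0.61 and camera adjusted p = 2.92e-07, including Angpt1 (-1.24) and Mycn (-0.84). Sort marker genes counted 0 higher and 3 lower of 8 (0 and 4 adjusted over the list alone), with a median log2 fold change of -0.50 and camera adjusted p = 3.97e-06, including Cd34 (-1.17) and Flt3 (-1.33). MYC target and ribosome biogenesis genes counted 0 higher and 27 lower of 42 (0 and 32 adjusted over the list alone), with a median log2 fold change of -0.39 and camera adjusted p = 4.99e-15, including Ppan (-0.81) and Dkc1 (-0.68). Egr1 was lower (-1.87), while the immediate early list counted 10 higher and 4 lower of 26 (13 and 4 adjusted over the list alone), with a median log2 fold change of 0.41 and camera adjusted p = 0.0572.

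Apobec1 (0.41 ± 0.13, adjusted p = 0.0362) passed in MPP2, but not without MIG replicate 2 (0.0825) or 3 (0.0555), and not with library size alone (0.177) or with no filter (0.0604). Myc (-0.26 ± 0.079, 0.0385) passed, but not without replicate 1 (0.0575) or 2 (0.0554). Ythdf2 (-0.11 ± 0.096, 0.488) and Son (0.062 ± 0.094, 0.730) did not pass. A fit of only these 4 libraries called 863 genes. Calls were 50.996% higher with TMM factors and 27.1% higher with library size alone, which moved the median of all genes to -0.13. With limma voom 63.8% of calls were higher, and of the calls of at least 2-fold 25.2% were higher.

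In MPP4, with 1 APOBEC-YTH library against 2 MIG libraries, Cd74 and H2-Ab1 of the MHC class II pathway and the neutrophil genes S100a8 and Mmp8 were higher. S100a8 (chromosome 3, 90669071 to 90670034), a subunit of calprotectin, had 173 CPM against 69.5 ± 7.22 (1.31 ± 0.18, adjusted p = 0.00415). Cd74 had 1019 against 475 ± 4.67 (1.10 ± 0.14, adjusted p = 0.00355). Jchain had 7 counts in the APOBEC-YTH library and 11.9 ± 1.76 CPM in MIG (-6.21 ± 0.73). In all, 78 of 15617 genes passed an adjusted p of 0.05, 48 higher and 30 lower, 39 of them by at least 2-fold. The share of calls that were higher was 61.5%, against 45.5% with DESeq2 and 40.8% in a fit of only the MPP4 libraries.

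Dendritic cell genes counted 4 higher and 0 lower of 26 (8 and 1 adjusted over the list alone), with a median log2 fold change of 0.39 and camera adjusted p = 1.42e-07, including H2-Ab1 (0.70). H2-Aa (1.01) was not called without MPP4 MIG replicate 2 (adjusted p = 0.0908), and H2-Eb1 (0.98) not without replicate 1 (0.0696) or 2 (0.0609). Granulocyte and monocyte genes counted 7 higher and 0 lower of 42 (14 and 0 adjusted over the list alone), with a median log2 fold change of 0.20 and camera adjusted p = 3.20e-12 (0.0979 with an estimated correlation), including Mmp8 (1.04). S100a9 (1.41), Lyz2 (0.70) and Klf2 (1.84) had adjusted p of 0.0506, 0.0587 and 0.0521 without MPP4 MIG replicate 1. Slfn4 (2.05), Pirb (1.42) and Lpl, which encodes lipoprotein lipase (1.35), were also higher, and Man2a1 was lower (-1.25). Cavin2 was higher too (3.11), but from a low level, since MPP4 MIG libraries had far less of it than HSC MIG libraries. Stress response genes counted 0 higher and 1 lower of 36 (0 and 2 adjusted over the list alone), with a median log2 fold change of -0.10 and camera adjusted p = 0.000593 (0.174 with an estimated correlation), and glycolysis genes 0 higher and 1 lower of 22 (0 and 3 adjusted over the list alone), with a median log2 fold change of -0.092 and camera adjusted p = 7.27e-05 (0.174 with an estimated correlation).

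Apobec1 (-0.062 ± 0.14, adjusted p = 0.925), Ythdf2 (0.053 ± 0.10, 0.906), Son (-0.38 ± 0.10, 0.129) and Myc (0.038 ± 0.083, 0.921) did not pass in MPP4, though Son did with DESeq2 (0.0194). The count of calls was 28 without either MIG replicate, 137 with no filter, 205 with limma voom, 376 with DESeq2 and 898 in a fit of only these 3 libraries.

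**Figure D2:**
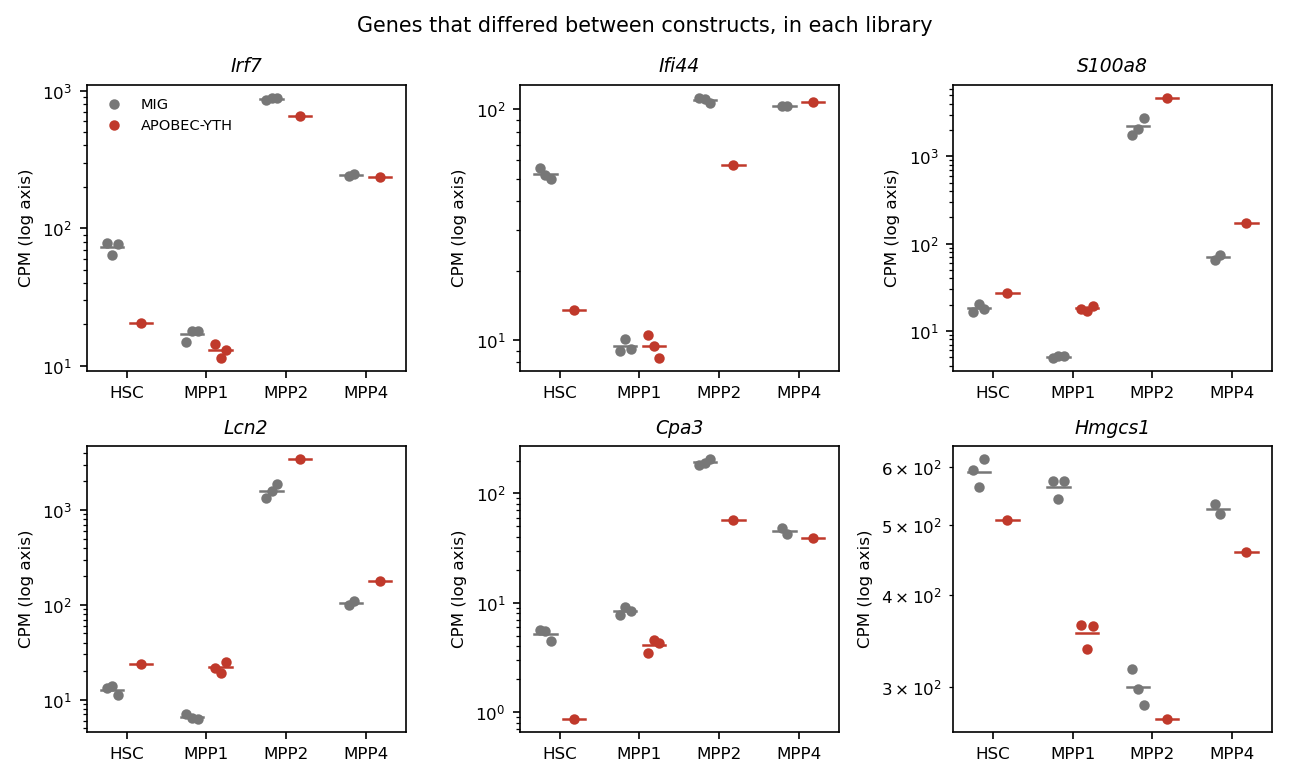
CPM of Irf7, Ifi44, S100a8, Lcn2, Cpa3 and Hmgcs1 in each library on a log axis, by population, with MIG libraries in grey, APOBEC-YTH libraries in red and a bar at each group's mean. Irf7 and Ifi44 separate the constructs in HSC, and the 3 red MPP1 libraries lie above the grey for S100a8 and Lcn2 and below them for Hmgcs1.

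Averaged over the 4 populations with equal weight, APOBEC-YTH libraries had lower interferon response genes and higher mitotic and immediate early genes. The interferon average came mostly from the lone HSC library, with medians of -0.76 in HSC, 0.023 in MPP1, -0.12 in MPP2 and -0.096 in MPP4. For G2 and M phase genes the medians were 0.29, 0.082, 0.42 and -0.020, and for immediate early genes 0.069 (or 0.099 at the bound), 0.17, 0.41 and 0.14, in the same order. Mast cell and ribosome biogenesis genes were also lower over 4 populations. Without MPP2 their camera adjusted p was 0.0275 and 0.00247, or 0.129 and 0.0763 with an estimated correlation. Ly6g, the surface marker of mouse neutrophils (1.79 ± 0.21), Chil3 (1.79 ± 0.15), Mmp9 (1.64), Ifitm6 (1.54), Gpnmb (1.66) and Slfn1 (1.68) were among the largest rises with 1 sign in every population. Slc45a3 (-1.78 ± 0.19), Cpa3 (-1.40 ± 0.087), the basophil protease gene Mcpt8 (-1.30), Nlrc3 (-1.15), Gas6 (-1.02) and Ephb6 (-0.94) were among the largest falls. In all, 2018 of 15617 genes passed an adjusted p of 0.05, 923 higher and 1095 lower, 176 of them by at least 2-fold. Because the MPP2 library stood apart, the average was also taken over HSC, MPP1 and MPP4, a choice made after seeing the data, and 820 genes were called.

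Interferon response genes counted 0 higher and 23 lower of 48 (1 and 32 adjusted over the list alone), with a median log2 fold change of -0.30 and camera adjusted p = 1.17e-18, and a median without MPP2 of -0.28, camera adjusted p = 4.77e-27 (6.56e-05 with an estimated correlation). Irf7 changed by -0.68, Ifi44 by -0.71 and Oasl1 by -0.82. G2 and M phase genes counted 26 higher and 1 lower of 51 (33 and 1 adjusted over the list alone), with a median log2 fold change of 0.19 and camera adjusted p = 6.46e-16, and without MPP2 0.13, camera adjusted p = 8.21e-07 (0.0145 with an estimated correlation). Mast cell, basophil and eosinophil genes counted 1 higher and 11 lower of 31 (1 and 13 adjusted over the list alone), with a median log2 fold change of -0.60 (or -0.56 with genes at 0 counts set at their bound) and camera adjusted p = 9.33e-08, and without MPP2 -0.34 (or -0.19 at the bound), camera adjusted p = 0.0275 (0.129 with an estimated correlation). MYC target and ribosome biogenesis genes counted 0 higher and 19 lower of 42 (1 and 27 adjusted over the list alone), with a median log2 fold change of -0.15 and camera adjusted p = 5.81e-11, and without MPP2 -0.085, camera adjusted p = 0.00247 (0.0763 with an estimated correlation). Immediate early genes counted 11 higher and 2 lower of 26 (12 and 3 adjusted over the list alone), with a median log2 fold change of 0.18 and camera adjusted p = 4.75e-07, and without MPP2 0.19 (or 0.28 at the bound), camera adjusted p = 1.85e-08 (0.0134 with an estimated correlation), including Junb (0.48) and Klf2 (1.37). Inflammatory genes counted 6 higher and 3 lower of 24 (9 and 3 adjusted over the list alone), with a median log2 fold change of 0.25 and camera adjusted p = 9.26e-05, and without MPP2 0.13, camera adjusted p = 5.21e-05 (0.0382 with an estimated correlation). Granulocyte and monocyte genes counted 17 higher and 10 lower of 42 (17 and 10 adjusted over the list alone), with a median log2 fold change of 0.11 and camera adjusted p = 1.61e-08 (0.0640 with an estimated correlation), including Ngp (1.31), Mmp8 (1.37) and Lcn2 (1.14). Without MPP2 the median of this list was 0.0042, with camera adjusted p = 0.00148 (0.262 with an estimated correlation). Megakaryocyte genes had a median log2 fold change of -0.020 (or 0.041 with genes at 0 counts set at their bound) and camera adjusted p = 0.0662 over 4 populations and 0.25, camera adjusted p = 3.37e-14 (0.00232 with an estimated correlation) without MPP2. Stem cell genes had a median log2 fold change of 0.041 and camera adjusted p = 0.976, and without MPP2 0.15, camera adjusted p = 5.21e-06 (0.00311 with an estimated correlation).

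Dntt (-1.92), Flt3 (-0.78) and Cd34 (-0.49) were lower on average. Apobec1 (0.029 ± 0.062, adjusted p = 0.857), Ythdf2 (0.034 ± 0.045, 0.713), Son (-0.13 ± 0.045, 0.0717) and Myc (-0.095 ± 0.037, 0.115) did not pass. Son passed without MPP2 (0.0390), with DESeq2 (0.0311), and without MPP1 APOBEC-YTH replicate 1 (0.0337) or MPP2 MIG replicate 3 (0.0266). Myc passed with library size alone (0.0482) and without MPP1 APOBEC-YTH replicate 2 (0.0247). Olr1 (1.93), Marchf1 (1.58), Ccl24 (-1.41) and Nwd1 (-1.03) also met the rule for large changes, but without MPP2 their adjusted p was 0.0651, 0.0651, 0.341 and 0.0556.

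The construct effect differed between populations for 1514 genes in a test of the 3 interaction contrasts. Among genes with at least 10 CPM in a group, the smallest p belonged to Scin, Gzmb, Serpina3g, Slc18a2, Gimap1, Anxa1, Serpina3f and Rab27b. Gzmb changed by -0.20 in HSC, 0.45 in MPP1, -2.09 in MPP2 and 0.43 in MPP4. Slc18a2, a vesicular monoamine transporter gene of mast cells, changed by 0.15 in HSC, 0.67 in MPP1, -1.42 in MPP2 and -0.039 in MPP4. Rab27b, a GTPase gene of platelet granule release, changed by 0.55 in HSC, 0.78 in MPP1, -1.11 in MPP2 and 0.12 in MPP4. Each contrast between populations includes a lone APOBEC-YTH library. A construct effect that differs between populations thus cannot be told apart from a difference of that library for another reason. Without MPP2, a choice made after seeing the data, 212 genes differed, and DESeq2 called 2920 over 4 populations.

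Calls nevertheless overlapped between populations, whose control libraries are separate. HSC and MPP1 shared 87 higher genes, against 5.41 for independent sets, and 65 lower genes, against 6.10. MPP1 and MPP2 shared 139 higher (expected 41.0) and 111 lower (expected 36.8). MPP1 and MPP4 shared 24 higher (expected 1.51) and 7 lower (expected 0.880). HSC and MPP2 shared 73 (expected 14.4) and 65 (expected 16.7), HSC and MPP4 9 (expected 0.529) and 1 (expected 0.3996), and MPP2 and MPP4 30 (expected 4.01) and 9 (expected 2.41). Of the 380 genes called in HSC, the share with the same sign was 82.4% in MPP1 (54.1% of all genes tested), 65.5% in MPP2 (55.3% of all genes tested) and 47.9% in MPP4 (42.4% of all genes tested). The expected numbers treat every gene as equally likely to be called. Genes with many counts and low spread are called more readily in every population, so part of the excess may come from that alone. Genes are not independent replicates, so the overlaps and shares carry no test.

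**Figure D3:**
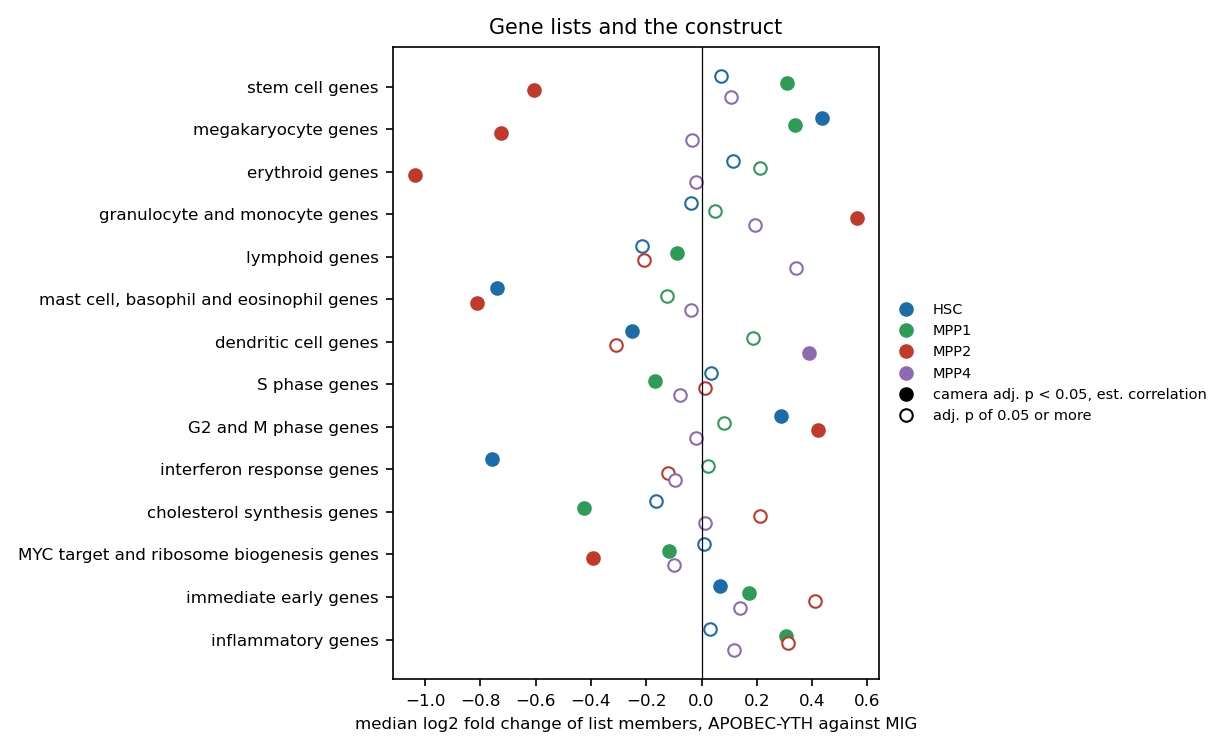
Median log2 fold change of APOBEC-YTH against MIG over the tested members of 14 gene lists, with 1 point per population. Filled points have a camera adjusted p under 0.05 with an estimated correlation and open points do not. The interferon point of HSC lies far left of the other populations, and MPP2 lies apart for the stem cell, megakaryocyte and erythroid lists.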

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

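Most tests in this part were chosen only after results were seen, and some of their bounds were set after values were known. The exceptions, written before their values, were the tests of gene length and of other splits of the libraries. A difference of the construct effect between populations drew attention to the results of the next 2 paragraphs. It was called for 1514 genes, and the medians below are differences of the log2 fold change over a list, with the camera adjusted p from an estimated correlation in parentheses.

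HSC minus MPP1 (99 genes called) gave interferon response -0.77 (1.61e-06), dendritic cell -0.52 (0.0102), mast cell -0.48 (0.0137, or -0.36 at the bound), stem cell -0.19 (0.00650), cholesterol synthesis 0.26 (0.00650), G2 and M phase 0.23 (0.00650), S phase 0.18 (0.0365) and MYC target and ribosome biogenesis genes 0.14 (0.0238). HSC minus MPP2 (1030 genes) gave erythroid 1.31 (0.0131, or 1.29 at the bound), megakaryocyte 1.18 (0.000451, or 1.11 at the bound), stem cell 0.62 (0.000631), MYC target 0.42 (0.000705), stress response 0.26 (0.0189), granulocyte -0.50 (0.0236) and interferon response genes -0.65 (0.000158). HSC minus MPP4 (210 genes) gave dendritic cell -0.80 (0.00390, or -0.86 at the bound), interferon response -0.62 (3.42e-05), granulocyte -0.48 (0.0476), sort marker -0.43 (0.0476, or -0.90 at the bound), G2 and M phase 0.36 (0.00390), stress response 0.27 (0.0386) and glycolysis genes 0.23 (0.0476).

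MPP1 minus MPP2 (1761 genes) gave erythroid 1.42 (0.00853, or 1.05 at the bound), megakaryocyte 1.22 (0.00104, or 1.199 at the bound), stem cell 0.93 (0.000109), sort marker 0.73 (0.0133), mast cell 0.72 (0.00418, or 0.80 at the bound), MYC target 0.31 (0.0102), stress response 0.29 (0.0382), G2 and M phase -0.32 (0.00523) and cholesterol synthesis genes -0.44 (0.00268). MPP1 minus MPP4 (101 genes) gave lymphoid -0.67 (0.0101), cholesterol synthesis -0.46 (0.00124), inflammatory 0.26 (0.0278), stress response 0.25 (0.0228), glycolysis 0.22 (0.0387), p53 target 0.16 (0.0228) and stem cell genes 0.14 (0.00724). MPP2 minus MPP4 (790 genes) gave dendritic cell -1.04 (0.00267, or -0.89 at the bound), megakaryocyte -0.96 (0.00293), sort marker -0.93 (0.00267), mast cell -0.60 (0.00293, or -0.61 at the bound), lymphoid -0.58 (0.0154, or -0.51 at the bound), MYC target -0.32 (0.00293), stem cell -0.30 (0.00170) and G2 and M phase genes 0.43 (0.00170). Where a second value is given, genes at 0 counts were set at their bound. Every difference in this and the previous paragraph includes a lone APOBEC-YTH library of HSC, MPP2 or MPP4. None can be told apart from a difference of such a library unrelated to the construct.

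A single high MIG library is not the source of the low interferon response genes in the HSC APOBEC-YTH library, since every MIG library lay above it by a median log2 difference of at least 0.739. Cells of the MPP2 kind in the HSC MIG libraries would have to make up 14.999% and bring 1790 CPM of Mpo, against 199 seen, and granulocyte genes reached a median of 0.152 of the level needed, which argues against them. The list's median log2 fold change was 0.023 in the replicated MPP1 comparison. This argues against the same log2 change by the construct in HSC and MPP1 as the whole source. MPP1 MIG libraries already had a median log2 difference of -0.189 to -0.223 from the HSC APOBEC-YTH library. An effect that lowers only raised interferon genes would have little to lower in MPP1, so the MPP1 value does not bear on it. The test of the difference (camera adjusted p = 1.61e-06 with an estimated correlation) had already flagged this result and adds no separate evidence. It rests on 1 HSC APOBEC-YTH library, so it cannot decide whether the construct itself acts alike in both. With 1 HSC APOBEC-YTH library, a difference of that library unrelated to the construct stays open. So does a rise shared by all HSC MIG libraries, which was not tested.

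In the fit of all libraries MPP2 had the most construct calls, from 1 APOBEC-YTH library, while fits of only the 2 groups compared called 863 in MPP2, fewer than in MPP1 (1417) or MPP4 (898). A wrong scaling factor of that library is not the source of the many calls in the fit of all libraries. The lowest number over factors from 0.5 to 2 times its TMM factor was 2559, against 949 in MPP1. The direction of the calls depends on the factor: 50.996% were higher with TMM and 27.1% of 2696 with library size alone. It depends on the method too, with 63.8% higher in limma voom. Genes of the longest and shortest tertiles by exon length differed by a median of 0.119, which argues against gene length, while GC content was not tested for want of a genome. Another mix of granulocytic and other cells fits, as would a shift of the same cells toward granulocytes: medians of all 5 lists of other blood cells were opposite in sign to the granulocyte list (0.56), namely mast cell -0.81, erythroid -1.04 (-0.99 at the bound), megakaryocyte -0.73 (-0.69 at the bound), dendritic cell -0.31 (-0.21 at the bound) and lymphoid -0.21 (-0.14 at the bound). Only 58.0% of genes called in MPP1 had the same sign in MPP2, which argues against an effect alike in both as the whole cause, and with 1 library (n = 1) a difference unrelated to the construct stays open.

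Neutrophil granule genes were higher in MPP1 APOBEC-YTH libraries, 9 of 12 called with a median log2 fold change of 1.80, and in each library by a median of at least 1.62, which fits every explanation below; all 12 had counts in MPP1 MIG, and Ngp had the highest level in APOBEC-YTH of those called, 42.2 CPM. Whether RNA or reads of the MPP2 APOBEC-YTH library, at 0.167% of reads, were the source could not be told. For 6 abundant genes outside the granule list the median rise was 0.544 times that needed, between the bounds of 0.5 and 0.7. The quartiles were 0.463 and 0.815. Among the 6, Chil3 (0.579) and Cybb (1.60) are known from neutrophils and could rise with the granule program too. The others were Lrg1 (0.893), Lipg (0.509), F10 (0.448) and Ly6c2 (0.080). The median thus cannot separate a carry-over of RNA or reads from a change of the program. The called rises of the mature-stage genes Retnlg (26.3 times the rise needed), Mmp9 (17.4) and Il1b (8.81) exceed what such RNA or reads would bring. That of Ccl6 (2.47) does not clearly (median of the 4, 13.1). These genes were taken because they were called higher. The rise needed was only 0.059 CPM for Il1b, 0.086 for Retnlg and 0.23 for Mmp9, so a called rise there would exceed it in any case. The result therefore does not bear on the granule genes. Mature neutrophils, which the sort of MPP1 would remove but which may arise in culture, could not be settled, since 45.5% of 11 mature-stage genes with counts in MPP1 had a log2 fold change above 0.5, between the 2 bounds, with Csf3r (-0.31) and Clec4d (-0.57) called lower and a median of 0.11. A change of the granule program in the cells and a small admixture of RNA, reads or cells both remain open.

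Other splits of the libraries into groups of the same sizes were also tested. The MPP1 construct comparison gave 949 calls against at most 1 in any other of 10 splits, MPP1 against HSC 2970 calls against at most 0 in any other of 10 splits, and MPP2 against HSC 8770 calls against at most 0 in any other of 10 splits. These 10 splits are too few for a share under 0.05. The averaged construct effect gave 2018 calls against at most 205 in any other of 40 splits. Its difference between populations gave 1514 calls against at most 382 in any other of 40 splits. In each, 1 of 40 splits reached the value, the real one, so a purely random division of the libraries is an unlikely source. Other splits mix constructs within a group, which widens its spread and lowers the calls. A lone APOBEC-YTH library that differed for another reason would also favor the real split. The splits thus cannot tell a construct effect from a difference of the lone libraries.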

How the results depend on the processing

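Averaging without MPP2 and comparing HSC, MPP1 and MPP4 alone were tests chosen only after results were seen. Counts of calls stayed within 1.5 times of the value given in the report under RLE size factors, library size alone and a filter of 1 CPM in 3 libraries. The cause was not tested for the changes that follow, except where fewer libraries or a stricter rule make the difference by construction. Requiring an absolute log2 fold change of 1 left 95, 128, 656 and 39 calls for the construct in HSC, MPP1, MPP2 and MPP4, 176 for its average, 585, 3817 and 2431 for MPP1, MPP2 and MPP4 against HSC, and 1556 for MPP4 against MPP2. Fits of only the groups compared called 27 in HSC, 1417 in MPP1, 863 in MPP2 and 898 in MPP4. DESeq2 called 1020 in HSC, 1535 in MPP1, 376 in MPP4 and 2920 for the difference between populations, and limma voom 706, 1628 and 205 in HSC, MPP1 and MPP4. No filter gave 137 in MPP4. APOBEC-YTH libraries alone gave 608 for MPP1 against HSC and 3903 for MPP4 against HSC. Without MPP2 the average called 820 and the difference 212.

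With library size alone, Rpsa (-0.11, from 0.21) and Rpl13a (-0.068, from 0.24) changed sign in MPP2 against HSC. Averaged without MPP2, Gimap1 (0.13, from -0.26), Angpt1 (0.11, from -0.23) and Slc40a1 (-0.023, from 0.29) did; the cause was not tested. The replicate block gave 36 calls in MPP4 and moved no other count by over 1.5 times (568 calls in HSC, 121 lists against 124). Libraries with 1 number did not deviate together (correlations -0.050 to 0.082), so the numbers were not taken as pairs. Leaving out 1 library gave 211 to 381 calls in HSC, 505 to 701 in MPP1, 2261 to 2633 in MPP2, 28 in MPP4, 1644 to 2276 for the average, 1114 to 1995 for the difference, 1905 to 2611, 8025 to 8471 and 4196 to 5313 for MPP1, MPP2 and MPP4 against HSC, and 3909 to 5311 for MPP4 against MPP2. The lone APOBEC-YTH libraries cannot be left out and are assumed to vary like the other groups. Of 124 list tests called, 75 stayed with an estimated correlation. Fry called 158, mixed fry 211 and library size alone 123. Of tests of named genes, DESeq2 left 962 on their side of the threshold, lost 5 and gained 76. Library size alone left 1020, lost 31 and gained 19. Over all left-out libraries 289 calls were lost and 44 gained, with 5625 unchanged.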

Other observations

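In MPP2 against HSC, genes that write, erase or read m6A counted 4 higher and 9 lower of 25 (4 and 9 adjusted over the list alone), with a median log2 fold change of -0.13 and camera adjusted p = 0.407, and the methyltransferase gene Mettl3 (-0.82), the reader genes Ythdf2 (-0.43) and Hnrnpa2b1 (-0.55) and G3bp1 (-0.46) were lower. In MPP4 against MPP2 they counted 8 higher and 1 lower of 25 (8 and 1 adjusted over the list alone), with a median log2 fold change of 0.18 and camera adjusted p = 0.0460 (0.175 with an estimated correlation), including Mettl3 (0.55) and Mettl14 (0.46). In MPP4 against HSC the demethylase gene Alkbh5 was higher (0.43). The averaged construct effect on the list counted 1 higher and 2 lower of 25 (1 and 2 adjusted over the list alone), with a median log2 fold change of 0.076 and camera adjusted p = 0.331. Cytidine and adenosine deaminase genes counted 4 higher and 5 lower of 13 (4 and 5 adjusted over the list alone) in MPP2 against HSC, with a median log2 fold change of -0.085 and camera adjusted p = 0.470, including Apobec1 (1.02), Dctd (-1.45) and Adarb1 (-2.79). In the MPP2 construct comparison Rbm47, a cofactor of Apobec1, rose by 1.02 and Cda changed by -1.79.

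Genes with reported m6A-dependent control in blood cells counted 14 higher and 9 lower of 30 (14 and 10 adjusted over the list alone) in MPP2 against HSC, with a median log2 fold change of 0.15 and camera adjusted p = 0.316, including Cebpa (3.38) and Rara (1.80). Their construct effect in MPP1 counted 4 higher and 0 lower of 30 (5 and 2 adjusted over the list alone), with a median log2 fold change of 0.043 and camera adjusted p = 0.0779, including Socs3 (0.56), and Gata2 was higher in HSC (0.49) and MPP1 (0.67) and lower in MPP2 (-0.72). T, B and NK cell genes, which would show mature lymphocytes, counted 4 higher and 1 lower of 9 (4 and 3 adjusted over the list alone) in MPP2 against HSC, with a median log2 fold change of 0.89 and camera adjusted p = 0.788. Stromal and endothelial genes counted 2 higher and 5 lower of 9 (2 and 5 adjusted over the list alone), with a median log2 fold change of -1.37 and camera adjusted p = 0.431. p53 target genes moved both ways in MPP4 against HSC, 5 higher and 19 lower of 33 (6 and 20 adjusted over the list alone), with a median log2 fold change of -0.36 and camera adjusted p = 0.00917, including Pmaip1 (2.03) and Phlda3 (-1.06).

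Ngp was higher in APOBEC-YTH than in MIG libraries of all 4 populations: 76.2 against 26.7 to 40.9 CPM in HSC, 37.05 to 51.05 against 9.97 to 11.6 in MPP1, 18831 against 7938 to 10165 in MPP2 and 342 against 172 to 173 in MPP4. Rn45s, the ribosomal RNA precursor, was lower in HSC (8721 against 10686 to 11931 CPM), MPP1 (7246 to 7609 against 10974 to 12975) and MPP4 (10745 against 13565 to 15189), and within the MIG range in MPP2 (15860.3 against 15466 to 17609). Both genes were chosen here after their values were seen. Xist had 2650 to 10236 counts in every library and Eif2s3y at most 2. The MPP2-labelled MIG libraries had 1.58 to 3.26 CPM of Slamf1 and 11154 to 11672 of Mpo. The 6 samples without counts could not be examined.

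Whether the construct moved MPP1 expression along the difference between MPP4 and HSC, in the HSC direction, was tested with a bound written before the value. In all, 671 genes were called both for the construct in MPP1 and in MPP4 against HSC, which share no library. Of these, 416 (62.0%) had a construct effect opposite in sign to MPP4 against HSC, as did 55.2% of all genes tested. The bound was 60%, so the prediction was met by a small margin, and the genes are not independent replicates. MPP1 levels were not compared with HSC levels here, so the count does not show that these genes came closer to HSC.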
